A study of Mus musculus with 39 samples.

How the data were processed

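Microglia, the resident macrophages of the brain, were isolated from newborn C57BL/6 mice, per the labels' protocols. One population, called donors, was plated at typically 250000 cells per well of a 24-well plate and given 1 µM alpha-synuclein, the protein that aggregates in Parkinson's disease, carrying the fluorescent dye Atto-488, for 14 h. The other population, called acceptors, was plated at typically 6000000 cells per T25 flask and stained for 15 min with a violet cell dye. The populations then shared a culture for 15, 30, 60, 150 or 300 min with no direct contact between them, and RNA was taken from each. The labels add the letters TW to the donor and acceptor groups without defining them. Donors and acceptors at 0 min and a control at 0 min complete the 13 groups of 3 libraries, 39 in all. What vessel and density the control had is not given in the sources used here. This series holds no donors or acceptors kept alone for the later times, so time in co-culture and time after handling are the same variable. Whether the 3 libraries of a group come from separate cultures or mice is not given in the sources used here, so the tests measure the spread between libraries.

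Libraries were made with the QuantSeq 3′ mRNA kit in its forward version, which reads a tag near the 3′ end of each polyadenylated transcript, and were sequenced as single reads of 100 bases, per the labels' protocols. The submitters' processing notes name STAR, Partek, DESeq2 and the mouse genome build mm10, without versions or roles. The authors deposited raw read counts per gene symbol for 16144 genes, and a second table of normalized counts. That table holds a normalized signal which the authors made with DESeq2, per the file headers. Checked over all genes, each library's raw and normalized values differ by 1 factor, between 0.614 and 1.40, so the normalization rescales whole libraries and changes no ratio between genes within one. A 3′ tag count does not grow with transcript length, so no length correction was made. Whether duplicate reads were removed, how reads shared by near-identical genes were counted and whether strand was used are not given in the sources used here. Values of genes with close copies or pseudogenes are therefore uncertain, as are values of genes that overlap others. Among the genes named or counted in lists here, those with close copies or pseudogenes include Fth1, Ubb, Hspa1a, Saa3 and the ribosomal protein genes. No mitochondrially encoded transcript is in the table, so the list fixed for them has 0 members measured and gave no result.

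Total reads per library ranged from 8649169 to 15910662, and 11951 to 13896 genes had reads. Levels are given in CPM, read counts scaled to a common library total. A floor of 3 counts corresponds to 0.181 to 0.414 CPM in single libraries. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Ribosomal RNA precursor Rn45s took 3.17% to 16.4% of the reads. Of the symbols, 96.5% matched the GENCODE M21 annotation of GRCm38, the assembly behind mm10, from which gene positions were taken; the files do not say where in a gene a tag lies.

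Raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with edgeR's default rule for the groups, which left 13034 genes holding 99.97% of the reads. TMM factors scaled the libraries, a quasi-likelihood model with 1 mean per group was fitted to all 39 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. The words called, rose, fell, higher and lower refer to this test. The biological coefficient of variation was 0.383. An exact permutation test of 3 against 3 libraries cannot give a p below 0.10, so no single comparison can be settled by permutation alone. CPM values use TMM-scaled totals and are given as mean ± SD of 3 libraries. Fold changes are fitted log2 values with a standard error (SE). The SE is the size of the log2 value divided by the square root of the test's F statistic. It is thus no measure of spread separate from the test. Where all libraries of a group had 0 counts, the fold is given as a lower bound against a floor of 3 counts over the group.

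Donors were compared with control and with acceptors at 0 min, acceptors with control at 0 min, each later time with 0 min of the same population, donors with acceptors at 300 min, and donors at 300 min with control. F tests asked for any change over the 6 times in each population and for a difference between their time courses. Before the data were examined, 30 gene lists were fixed: inflammatory mediators, NF-kB pathway targets, interferon response, immediate early genes, homeostatic microglia, disease-associated microglia, lysosome, autophagy, endocytosis and phagocytosis receptors, oxidative stress (NRF2), heat shock and chaperones, unfolded protein and integrated stress response, proteasome and ubiquitin, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded transcripts, cholesterol synthesis, cholesterol efflux (LXR), cell cycle, apoptosis and p53, actin and membrane tubes, inflammasome and pyroptosis, ribosomal proteins, nuclear and long noncoding RNAs, and markers of astrocytes, oligodendrocyte lineage, neurons, fibroblasts and vessels, other immune cells and border macrophages. Lists were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 29 lists and 13 comparisons (377 tests), and again with the correlation estimated from the data.

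The rule for named genes was also fixed before the data were examined. It draws on called genes with a mean of at least 5 CPM and no overlap between the groups, passing over predicted genes. It takes the 10 largest rises and 10 largest falls in donors against control at 0 min, donors at 300 against 0 min, acceptors at 300 against 0 min and donors against acceptors at 300 min. In the other comparisons it takes 3 of each. It adds up to 4 called members of each list with the smallest adjusted p, or the member with the highest mean CPM where none was called. Tnf, Il1b, Nfkbia, Tnfaip2, Hmox1, P2ry12, Apoe and Fos may be named throughout.

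Alternatives planned beforehand were DESeq2 1.42.0, limma on the deposited normalized counts with a pseudocount of 1, RLE scaling, no filter on low counts and a filter of 1 CPM in 3 libraries. Further ones were a fit to the compared groups alone, a block for runs of library numbers, and leaving out each library in turn. Scaling by total counts, leaving out Rn45s and leaving out 1 acceptor library were added after seeing the data. The library numbers fall in 3 runs of 13 with 1 library of each group. All 3 pairs of a run had correlated deviations, over 0.1, in 10 of 15 comparisons, among them each comparison over time in acceptors. By the rule fixed beforehand the runs pair these libraries, so a blocked value stands beside their results where it changes a call or count. Without TMM factors the median log2 change of all genes moved by −0.34 for donors against control at 0 min and by −0.19 for donors against acceptors at 300 min. All directions are relative to TMM scaling, and where total-count scaling turns a direction this is said. The tests were tried on simulated counts with 200 genes changed. Each gene's counts were drawn independently from a count model with its mean over all 39 libraries and its estimated spread. They hold no runs, no correlation between genes and no outlying library, so the numbers of false calls do not cover such structure. For donors against control at 0 min, edgeR recovered 21 of 98 genes changed 2-fold and 62 of 99 changed 4-fold, and called 0 of the unchanged genes among 12756 genes tested (DESeq2 called 10, limma 2). For donors at 300 against 0 min it recovered 30 of 99 and 67 of 98, with 6 unchanged genes called, and for acceptors at 300 against 0 min 23 of 100 and 52 of 94, with 2 called. The adjustment is stricter where fewer genes change, and 200 were changed here. In comparisons over time, where few genes were called, the shares recovered may therefore be lower. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.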

Results

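The series measured messenger RNA at 3′ ends in 39 libraries of primary mouse microglia. The 18 donor libraries, from cells given alpha-synuclein, and the 18 acceptor libraries cover 0, 15, 30, 60, 150 and 300 min of co-culture without direct contact. Each time has 3 libraries, and 3 control libraries stand at 0 min. Total reads were 10249066 to 11587525 per library in the control, 8649169 to 14743934 in acceptors and 8753743 to 15910662 in donors. TMM factors were 0.828 to 0.927 in donors, 0.883 to 1.23 in acceptors and 1.08 to 1.17 in the control, so donors and the other groups did not overlap in them except for 1 acceptor library. That library, acceptors at 300 min replicate 2, had the fewest reads and the fewest genes with reads (11951) of the 39, and counts that move by over 1.5 times without it are also given without it. On the first principal component, which held 38.1% of the variance, donors lay between 51.2 and 68.8, acceptors between −75.0 and −38.8 and the control between −73.7 and −30.9. Pearson correlations between libraries of a group were 0.899 to 0.969 on the log scale.

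The comparison of donors with control at 0 min asks what differed in microglia after alpha-synuclein, before any co-culture. Lcn2, the iron-carrier binding protein lipocalin 2 (chromosome 2, 32384633 to 32388252, GRCm38), had 982 ± 189 CPM in donors and 0.500 ± 0.364 in the control (SD, n = 3 each). Il1rn, the interleukin-1 receptor antagonist, had 9970 ± 1493 against 551 ± 211 CPM, and Il1a, the cytokine interleukin-1 alpha, 111 ± 68.8 against 0.935 ± 0.284. Il12b, a subunit of interleukins 12 and 23, Upp1, a uridine phosphorylase, and the cytokine gene Il19 had no reads in the control. Against a floor of 3 counts over the group they were at least 1546-fold, 1172-fold and 275-fold higher in donors. Il12b had 125 ± 120 CPM in donors, and without donor replicate 3, at 263 CPM, its bound fell to 695-fold. Timp1, an inhibitor of matrix metalloproteinases, was 7.31 ± 0.81 log2 units higher (SE). In the other direction Cx3cr1, the fractalkine receptor of microglia (chromosome 9, 119901616 to 120069879), had 6.75 ± 1.57 CPM in donors and 286 ± 216 in the control. Csf1r, the receptor that microglia need for survival (chromosome 18, 61100598 to 61132149), had 455 ± 97.1 against 2780 ± 510. Rasgrp3, an activator of Ras proteins, fell by 6.10 ± 0.70 log2 units, Hpgd, which degrades prostaglandins, by 5.30 ± 0.75, and the ribonuclease gene Rnase6 by 6.49 ± 1.09.

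Of 13034 genes tested, 2565 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1348 higher and 1217 lower in donors, and 1772 of them changed at least 2-fold. The adjusted p was 4.03e-13 for Lcn2, 9.54e-11 for Il1rn, 2.05e-07 for Cx3cr1 and 2.60e-07 for Csf1r, and the 3 donor values lay on the same side of the 3 control values for each. Scaled by total counts, 3362 genes were called, of which 739 were higher. Without control replicate 2 the count was 1664, and the alpha-synuclein of the donors came with a vessel and density that the control may not have shared.

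Of the list of inflammatory mediators, 16 of 27 tested members rose and 0 fell, against 17 and 1 adjusted over the list alone, and the list ranked higher than other genes (camera adjusted p = 5.18e-11; adjusted p = 0.523 with an estimated correlation). Il1b, the cytokine interleukin-1 beta (chromosome 2, 129364570 to 129371139), had 1109 ± 624 against 243 ± 185 CPM (2.19 ± 0.69 log2 units, edgeR Benjamini-Hochberg adjusted p = 0.0228). The call was lost without control replicate 2, without donor replicate 3 and in the fit to these 6 libraries, and its adjusted p-values over the alternatives were 1.10e-04 to 0.133. Tnf, the cytokine tumour necrosis factor, had 129 ± 54.0 against 179 ± 105 CPM and was not called. Of the NF-kB pathway targets 15 of 35 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.00536; adjusted p = 0.997 with an estimated correlation), or 9 and 4 with total-count scaling. Among them, Cd40, a costimulatory receptor, was 3.28 ± 0.59 log2 units higher and Zc3h12a, a ribonuclease that cleaves cytokine messages, 1.73 ± 0.28, while Tlr2, a receptor for bacterial lipoproteins, fell by 1.59 ± 0.28. Nfkbia, the inhibitor of NF-kB, had 601 ± 76.9 against 610 ± 251 CPM and Tnfaip2 264 ± 26.2 against 196 ± 71.6, neither called.

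Of the interferon response, 11 of 42 members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.93e-04; adjusted p = 0.997 with an estimated correlation). With total-count scaling 6 rose and 1 fell. The chemokine gene Cxcl9 was 4.07 ± 0.71 log2 units higher, Gbp2, a GTPase induced by interferons, 2.21 ± 0.49, and Isg15, a ubiquitin-like protein, 2.01 ± 0.47. Of the list inflammasome and pyroptosis, 7 of 19 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.0428; adjusted p = 0.686 with an estimated correlation), or 5 and 2 with total-count scaling. P2rx7, an ATP-gated channel, rose by 1.53 ± 0.28 log2 units and the cytokine gene Il18 by 1.82 ± 0.43. Of the immediate early genes 15 of 37 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 0.00115; adjusted p = 0.686 with an estimated correlation). Gadd45b, a stress-response gene, rose by 3.87 ± 0.33 log2 units and the transcription factor gene Atf3 by 1.97 ± 0.28, whereas Egr2, a transcription factor, fell by 2.12 ± 0.36. Fos had 127 ± 73.3 against 82.1 ± 16.4 CPM and was not called.

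The list that held under both correlations was glycolysis and hypoxia, with 18 of 31 members higher and 0 lower (22 and 1 adjusted over the list alone; camera adjusted p = 4.49e-13; adjusted p = 0.0258 with an estimated correlation). Hilpda, a lipid droplet protein induced by low oxygen, had 939 ± 271 against 41.6 ± 1.77 CPM. Bnip3, a mitophagy receptor, rose by 3.59 ± 0.29 log2 units, Pfkfb3, which makes an activator of glycolysis, by 2.66 ± 0.29, and Slc16a3, a lactate exporter, by 2.38 ± 0.32. Of the oxidative stress (NRF2) list 13 of 31 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.45e-04; adjusted p = 0.997 with an estimated correlation), or 8 and 2 with total-count scaling. Hmox1, the heme-degrading enzyme (chromosome 8, 75093621 to 75100589), had 351 ± 64.2 against 29.9 ± 10.4 CPM (3.55 ± 0.27 log2 units, edgeR Benjamini-Hochberg adjusted p = 1.36e-11), and the ferritin heavy chain gene Fth1 rose by 1.62 ± 0.26 log2 units. In oxidative phosphorylation 1 of 59 rose and 1 fell, 0 and 0 adjusted over the list alone (camera adjusted p = 0.287), while total-count scaling called 0 higher and 22 lower.

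Of the proteasome and ubiquitin list 13 of 40 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.98e-04; adjusted p = 0.997 with an estimated correlation). With total-count scaling 4 rose, and in the fit to these 6 libraries 6 rose, with 0 lower in each. Psmd11, a proteasome lid subunit, rose by 1.22 ± 0.28 log2 units and Ubb, a ubiquitin gene, by 1.07 ± 0.22. Of the autophagy list 13 of 44 rose and 3 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.0227; adjusted p = 0.717 with an estimated correlation), a balance that total-count scaling turned to 7 and 7. Tax1bp1, an autophagy receptor for ubiquitin-tagged cargo, had 247 ± 5.34 against 104 ± 17.3 CPM, and Vps18, a subunit of a complex that tethers vesicles to lysosomes, 78.3 ± 10.9 against 24.7 ± 5.77. In the lysosome list 13 of 48 rose and 7 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.881), but with total-count scaling 5 rose and 14 fell, and in the fit to these 6 libraries 8 rose and 6 fell. Hexa, a subunit of the enzyme that degrades gangliosides, fell by 1.74 ± 0.13 log2 units and Man2b1, a lysosomal mannosidase, by 1.36 ± 0.18. Gla, a lysosomal galactosidase, rose by 1.28 ± 0.22 and Atp6v0d1, a subunit of the lysosomal proton pump, by 1.00 ± 0.16.

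Of the endocytosis and phagocytosis receptors 8 of 33 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.584), and with total-count scaling 6 rose and 10 fell. Fcgr3, a receptor for antibodies, rose by 2.03 ± 0.25 log2 units and the scavenger receptor gene Msr1 by 1.84 ± 0.28, whereas Clec7a, a receptor for fungal glucans, fell by 2.12 ± 0.34. In heat shock and chaperones 6 of 30 rose and 1 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.127), turned to 3 and 5 by total-count scaling and evened to 4 and 3 in the fit to these 6 libraries. The chaperone gene Hsp90aa1 rose by 1.37 ± 0.22 log2 units. In the unfolded protein and integrated stress response 7 of 33 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.136), or 4 and 3 with total-count scaling. The amino acid transporter gene Slc3a2 rose by 1.58 ± 0.33 log2 units. In apoptosis and p53, 7 of 32 rose and 7 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.952). The list's mean had the opposite sign to its median and test. Total-count scaling called 1 higher and 8 lower, and the fit to these 6 libraries 4 and 6. Mdm2, the ligase that removes p53, rose by 1.21 ± 0.21 log2 units and the p53 target gene Phlda3 fell by 1.74 ± 0.31.

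Most called members of the lists of microglial states were lower in donors. Of the homeostatic microglia list 11 of 24 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00536; adjusted p = 0.148 with an estimated correlation). P2ry13, a purine receptor, fell by 2.15 ± 0.38 log2 units, and Rhob, a small GTPase, was among those that rose, by 1.24 ± 0.22. P2ry12, another purine receptor, had 1.95 ± 0.153 against 5.06 ± 1.32 CPM and was not called. Of the disease-associated microglia list 8 of 28 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.00503; adjusted p = 0.739 with an estimated correlation). Trem2, a lipid-sensing receptor, had 67.4 ± 10.6 against 296 ± 132 CPM, Lpl, lipoprotein lipase, 914 ± 121 against 4573 ± 559, and the growth factor gene Igf1 fell by 1.71 ± 0.24 log2 units. Apoe, a lipid carrier, was not called at 10744 ± 5526 against 16045 ± 8328 CPM. Within each run of library numbers it was lower in donors, at 7528 against 11352.5, 7578 against 11123 and 17125 against 25660 CPM. The rule did not pair this comparison. Of the border macrophage markers 4 of 11 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.101), among them Mrc1, the mannose receptor, by 2.31 ± 0.60 log2 units.

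Of the cell cycle list 15 of 38 fell and 1 rose (17 and 3 adjusted over the list alone; camera adjusted p = 9.88e-06; adjusted p = 0.686 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell by 4.46 ± 0.76 log2 units and Mcm6, a subunit of the replicative helicase, by 1.24 ± 0.20. Of the cholesterol synthesis list 7 of 23 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.0200; adjusted p = 0.997 with an estimated correlation), or 13 fell and 0 rose with total-count scaling. Fdps, farnesyl diphosphate synthase, fell by 1.40 ± 0.34 log2 units. Of the cholesterol efflux (LXR) list 1 of 15 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.598), or 1 and 4 with total-count scaling. Fasn, fatty acid synthase, fell by 1.80 ± 0.26 log2 units and Plin2, which coats lipid droplets, rose by 1.43 ± 0.33. In actin and membrane tubes 3 of 45 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.559), with 2 and 5 under total-count scaling. Of the ribosomal proteins 0 of 48 rose and 1 fell, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0561), but total-count scaling called 22 lower. Of the nuclear and long noncoding RNAs 0 of 15 were called by edgeR, 0 adjusted over the list alone (camera adjusted p = 0.723), and total-count scaling called 3 lower.

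Markers of other cells were mostly lower or not called. Of astrocyte markers 2 of 13 fell (1 adjusted over the list alone; camera adjusted p = 0.316). Of oligodendrocyte lineage markers 2 of 14 (1 adjusted over the list alone; camera adjusted p = 0.316) fell, and of neuron markers 1 of 11 (0 adjusted over the list alone; camera adjusted p = 0.474), with 0 higher in all 3 lists. Mbp, a myelin protein, fell by 1.38 ± 0.27 log2 units. Of fibroblast and vascular markers 2 of 13 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.694). Dcn, a matrix proteoglycan, had 7.60 ± 3.11 CPM in donors and no reads in the control. Of other immune cell markers 1 of 6 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.952), the list's median and mean having the opposite sign to its test. The member that rose was S100a8, a calcium-binding protein of neutrophils and activated myeloid cells, at 48.6 ± 40.5 against 0.414 ± 0.717 CPM.

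**Figure D1:**
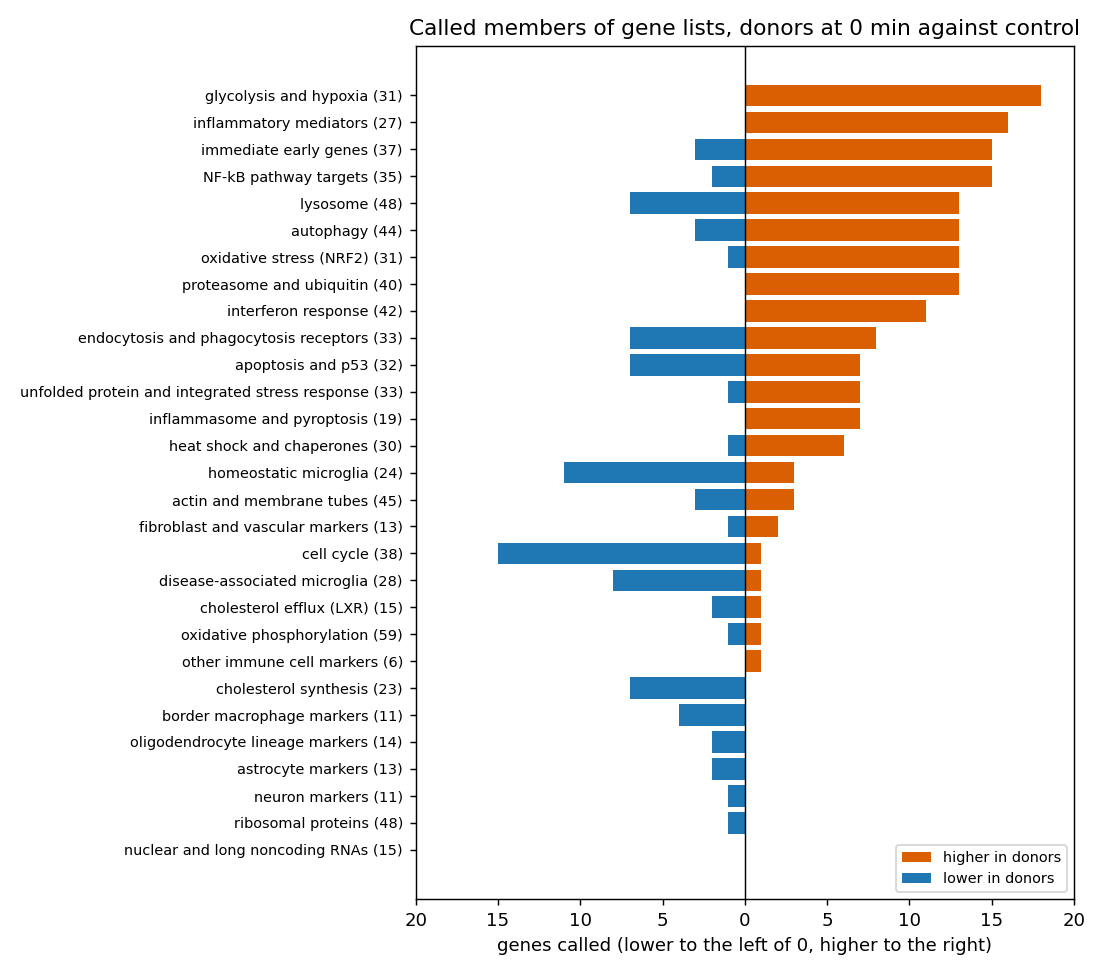
Number of genes called in each of 29 lists (number of members tested in parentheses) in donors against control at 0 min, with members higher in donors drawn to the right of 0 and members lower drawn to the left. Glycolysis and hypoxia has 18 members higher and 0 lower, and cell cycle has 1 higher and 15 lower; with total-count scaling the balance turns for lysosome, heat shock and chaperones, and endocytosis and phagocytosis receptors, and autophagy becomes even.

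Acceptors were set against the control at 0 min to ask whether the population differed before co-culture. Csf1r had 2846 ± 178 CPM in acceptors and 2780 ± 510 in the control, Hmox1 30.1 ± 8.77 and 29.9 ± 10.4, and Il1b 91.7 ± 36 and 243 ± 185 (SD, n = 3 each). By edgeR 0 genes were called, with 263 at an unadjusted p under 0.05, and DESeq2 and limma called 0 each. As lists, inflammatory mediators (camera adjusted p = 0.00179), interferon response (0.00319), NF-kB pathway targets (0.0213) and immediate early genes (0.0497) ranked lower in acceptors, with 0 members called, also adjusted over the list alone. Each had an adjusted p = 0.997 with an estimated correlation.

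Donors and acceptors at 0 min differed in the genes that led the comparison with the control. Lcn2 had 1.16 ± 1.36 CPM in acceptors and was 9.65 ± 0.66 log2 units higher in donors, Il1b was higher with an edgeR Benjamini-Hochberg adjusted p of 4.72e-04, and Cx3cr1 fell by 5.68 ± 0.66 log2 units relative to acceptors. In all 2975 genes were called, 1576 higher and 1399 lower in donors, or 879 higher of 3552 with total-count scaling. Without acceptor replicate 2 at 0 min the count was 1954.

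Over co-culture, donor genes were followed to ask whether the population moved away from its starting state. Lcn2 had 1049 ± 167 CPM at 300 min, Saa3, an acute-phase protein, 44913 ± 2771 against 45957 ± 11989 at 0 min, Hmox1 328 ± 55.0 and Il1b 1106 ± 869. Fos had 64.5 ± 18.0 CPM at 300 min against 127 ± 73.3 at 0 min and was not called. By edgeR 0 genes were called at 15, 30, 60, 150 or 300 min against 0 min, with 227, 198, 317, 330 and 605 at an unadjusted p under 0.05, and DESeq2 and limma called 0 at each time. The fit with a block for library-number runs called 1 gene at 300 min. The F test over the 6 times called 0 genes (252 at an unadjusted p under 0.05), with 1 by DESeq2 and 0 by limma.

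Lists in donors shifted at some times, with 0 members called in any of them, also adjusted over the list alone. Immediate early genes ranked higher at 30 min (camera adjusted p = 0.00748; adjusted p = 0.867 with an estimated correlation) and lower at 300 min (camera adjusted p = 5.45e-05; adjusted p = 0.443 with an estimated correlation). At 300 min ribosomal proteins (0.00725), proteasome and ubiquitin (0.0313) and disease-associated microglia (0.0388) also ranked lower, each with an adjusted p = 0.997 with an estimated correlation. At 150 min neuron markers (0.00725) and oligodendrocyte lineage markers (0.0124) ranked higher, each with an adjusted p = 0.997 with an estimated correlation. Endocytosis and phagocytosis receptors ranked lower then (camera adjusted p = 0.0442; adjusted p = 0.184 with an estimated correlation). With the replicate block oligodendrocyte lineage markers ranked higher at 300 min too (adjusted p = 0.0197; 0.0581 without the block, and 0.997 with an estimated correlation).

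In acceptors, Cytip and Vegfa rose. Cytip, which binds the integrin-regulating protein cytohesin-1 (chromosome 2, 58129137 to 58195532), had 7.32 ± 3.74 CPM at 0 min, 9.61 ± 3.54 at 15 min and 23.4 ± 4.33 at 30 min. It had 48.7 ± 9.12 at 60 min, 85 ± 23 at 150 min and 62.5 ± 13 at 300 min (SD, n = 3 each). Vegfa, the vascular endothelial growth factor (chromosome 17, 46016993 to 46032369), had 4.73 ± 1.28, 5.87 ± 3.26, 11 ± 1.30, 24.9 ± 7.97, 21.8 ± 2.13 and 12.9 ± 3.0 CPM at the same times. The control had 5.13 ± 6.24 CPM of Cytip and 5.06 ± 0.618 of Vegfa. In donors Cytip had 22.5 ± 0.584 CPM at 0 min and 9.10 ± 2.04 at 300 min, and Vegfa 25.4 ± 11.4 and 17.6 ± 6.30.

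By edgeR with Benjamini-Hochberg adjustment, Vegfa was the 1 gene called at 60 min (2.39 ± 0.38 log2 units, adjusted p = 0.00548). Cytip (3.54 ± 0.56, 0.00450) and Vegfa (2.20 ± 0.38, 0.0116) were the 2 at 150 min and Cytip (3.09 ± 0.55, 0.0365) the 1 at 300 min, all values at these times lying above all values at 0 min. At 15 and 30 min 0 genes were called, with 165 and 151 at an unadjusted p under 0.05, and DESeq2 and limma called 0 each. The F test over time called the same 2 genes (adjusted p = 0.00236 each), as did the test for time courses that differ between donors and acceptors (Cytip 0.00732, Vegfa 0.0150). DESeq2 called 6, 5 and 5 genes at 60, 150 and 300 min and 34 over time. With the replicate block of library-number runs 2 genes were called at 60 min, 8 at 150 min, 1 at 300 min and 8 over time, and 4 had different time courses. The runs pair these libraries by the rule, so Cytip and Vegfa cannot be taken as the only genes that changed. The count at 60 min became 0 without replicate 2 at 60 min and without replicates 2 or 3 at 0 min, and 2 without replicate 1 at 60 min. The count at 150 min became 0 without replicates 1 or 3 at 0 min and 1 without replicate 2 at 0 min. The count at 300 min became 0 without the doubted replicate 2, without replicate 1 and without any of the 3 libraries at 0 min, and 19 without replicate 3. It was also 0 by limma, with total-count scaling and in the fit to the 6 libraries alone, and fits to the compared groups alone called 5 genes at 60 min and 1 over time. Without the doubted library the 2 genes over time and the 2 with different time courses remained.

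Immediate early genes, which respond to stimuli without new protein synthesis, moved as a list in acceptors. They ranked higher than other genes at 15 min (camera adjusted p = 0.00680; adjusted p = 0.846 with an estimated correlation) and at 30 min (7.03e-12; adjusted p = 0.0295 with an estimated correlation). The same held at 60 min (4.49e-13; adjusted p = 0.0258 with an estimated correlation) and at 150 min (0.0292; adjusted p = 0.997 with an estimated correlation). Of the 37 members 0 were called by edgeR over all genes, and adjusted over the list alone 4 were called at 30 min, 9 at 60 min and 1 at 150 min. Fos had 76.4 ± 4.43 CPM at 0 min, 178 ± 22.2 at 30 min and 197 ± 36.8 at 60 min, without a call over all genes. Fosl2, a Fos-family factor chosen after its values were seen, had 18.5 ± 6.54 CPM at 0 min and 78.5 ± 24.2 at 60 min. Glycolysis and hypoxia ranked higher at 300 min (camera adjusted p = 0.00179; adjusted p = 0.686 with an estimated correlation), with 0 of 31 members called and 2 adjusted over the list alone. With the replicate block it also ranked higher at 150 min (adjusted p = 0.0495; 0.0679 without the block), and oxidative stress (NRF2) lower at 30 min (0.0466; 0.0876 without the block), each with an adjusted p = 0.997 with an estimated correlation.

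**Figure D2:**
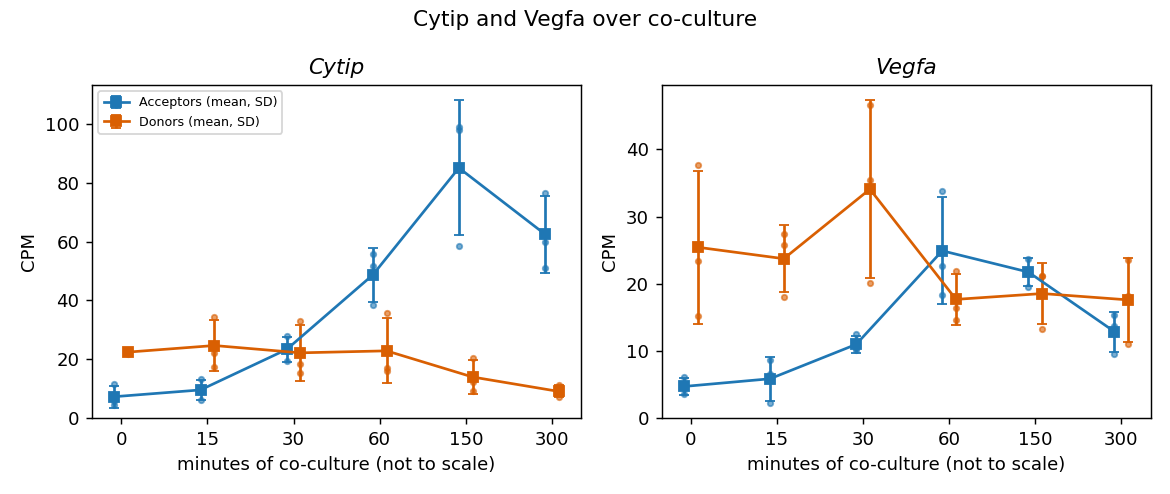
CPM of Cytip and Vegfa (vertical axes) over minutes of co-culture (horizontal axes, not to scale) in acceptors and donors, with small points for single libraries, squares for the mean of 3 libraries and bars for the SD. Cytip in acceptors goes from 7.32 CPM at 0 min to 85 at 150 min, while Vegfa goes from 4.73 CPM at 0 min to 24.9 at 60 min.

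At 300 min donors and acceptors were compared to ask whether they still differed after co-culture. Lcn2 had 1049 ± 167 CPM in donors and 2.12 ± 1.46 in acceptors (SD, n = 3 each; 8.94 ± 0.63 log2 units, edgeR Benjamini-Hochberg adjusted p = 4.55e-12). Slamf1, a receptor of immune cells, had no reads in acceptors and was at least 551-fold higher in donors, and Hmox1 was 3.01 ± 0.26 log2 units higher. Cx3cr1 fell by 4.86 ± 0.63 log2 units relative to acceptors, Csf1r by 3.17 ± 0.33, Trem2 by 2.74 ± 0.31 and S100a4, a calcium-binding protein, by 4.24 ± 0.34. Il1b had 1106 ± 869 against 266 ± 155 CPM (adjusted p = 0.0284), a call lost without donor replicate 1, without acceptor replicate 1 and without the doubted acceptor replicate 2, with adjusted p-values of 0.00121 to 0.239 over the alternatives. In all 3002 genes were called, 1487 higher and 1515 lower, or 1007 higher of 3269 with total-count scaling. Without the doubted acceptor library the count was 2513, of which 1331 were higher, and the fit to the 6 libraries alone called 719.

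Of the lists at 300 min, glycolysis and hypoxia had 18 of 31 members higher and 0 lower (21 and 0 adjusted over the list alone; camera adjusted p = 2.14e-10). Homeostatic microglia had 10 of 24 lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 8.23e-04). Each of these had an adjusted p = 0.0407 with an estimated correlation. Pfkfb3 was 3.06 ± 0.30 log2 units higher in donors. Inflammatory mediators had 18 of 27 higher and 0 lower (19 and 0 adjusted over the list alone; camera adjusted p = 4.49e-13; adjusted p = 0.443 with an estimated correlation), with Il1rn higher by 4.30 ± 0.35 log2 units. Disease-associated microglia had 9 of 28 lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 1.65e-04; adjusted p = 0.443 with an estimated correlation). Border macrophage markers had 7 of 11 lower and 0 higher, likewise adjusted over the list alone (camera adjusted p = 0.0275; adjusted p = 0.770 with an estimated correlation). NF-kB pathway targets (13 higher, 1 lower), interferon response (13 and 0), oxidative stress (NRF2; 10 and 2), heat shock and chaperones (9 and 2) and proteasome and ubiquitin (12 and 0) also ranked higher. Adjusted over the list alone the counts were 14 and 1, 15 and 0, 11 and 2, 10 and 2, and 13 and 0, each list with an adjusted p = 0.997 with an estimated correlation. Cell cycle (2 higher, 13 lower), cholesterol synthesis (0 and 8), oxidative phosphorylation (0 and 14) and ribosomal proteins (0 and 14) ranked lower. Adjusted over the list alone the counts were 2 and 13, 0 and 10, 0 and 16, and 0 and 14, each list with an adjusted p = 0.997 with an estimated correlation. Without the doubted library, which had the fewest genes with reads, oxidative phosphorylation had 1 higher and 7 lower, NF-kB pathway targets 14 and 2, oxidative stress 8 and 1, and cell cycle 1 and 15. The fit to the 6 libraries alone called 0 members of proteasome and ubiquitin, oxidative phosphorylation and cholesterol synthesis, and 1 each of the ribosomal proteins and border macrophage markers, both lower. In that fit 8 of glycolysis and hypoxia, 6 of oxidative stress and 3 of heat shock and chaperones were higher, and 5 of homeostatic microglia and 6 of cell cycle were lower. With total-count scaling proteasome and ubiquitin had 6 higher and 2 lower, oxidative phosphorylation 0 and 23, heat shock and chaperones 6 and 3, oxidative stress 8 and 3, and NF-kB pathway targets 13 and 3.

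The differences between donors and acceptors at 0 and 300 min share no libraries. They do share the fit, the runs of library numbers and the vessels, densities, dyes and alpha-synuclein that set the populations apart. The counts for independent lists are therefore a reference and not a test. Of the genes called higher at 0 min 1100, among them Lcn2 and Il12b, were called higher again at 300 min, where independent lists would share 179.8. Another 932 were called lower at both times, among them Cx3cr1 and Rnase6, where independent lists would share 162.6. Together 2032 genes were called the same way at both times and 1 the opposite way, and the fits to the compared groups alone share 659. Without the doubted library 1980 genes were called at both times. Set against the control, donors at 300 min had 2356 genes called by edgeR, 1287 higher and 1069 lower, or 747 higher of 2934 with total-count scaling. Il12b and Upp1 again led the rises.

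**Figure D3:**
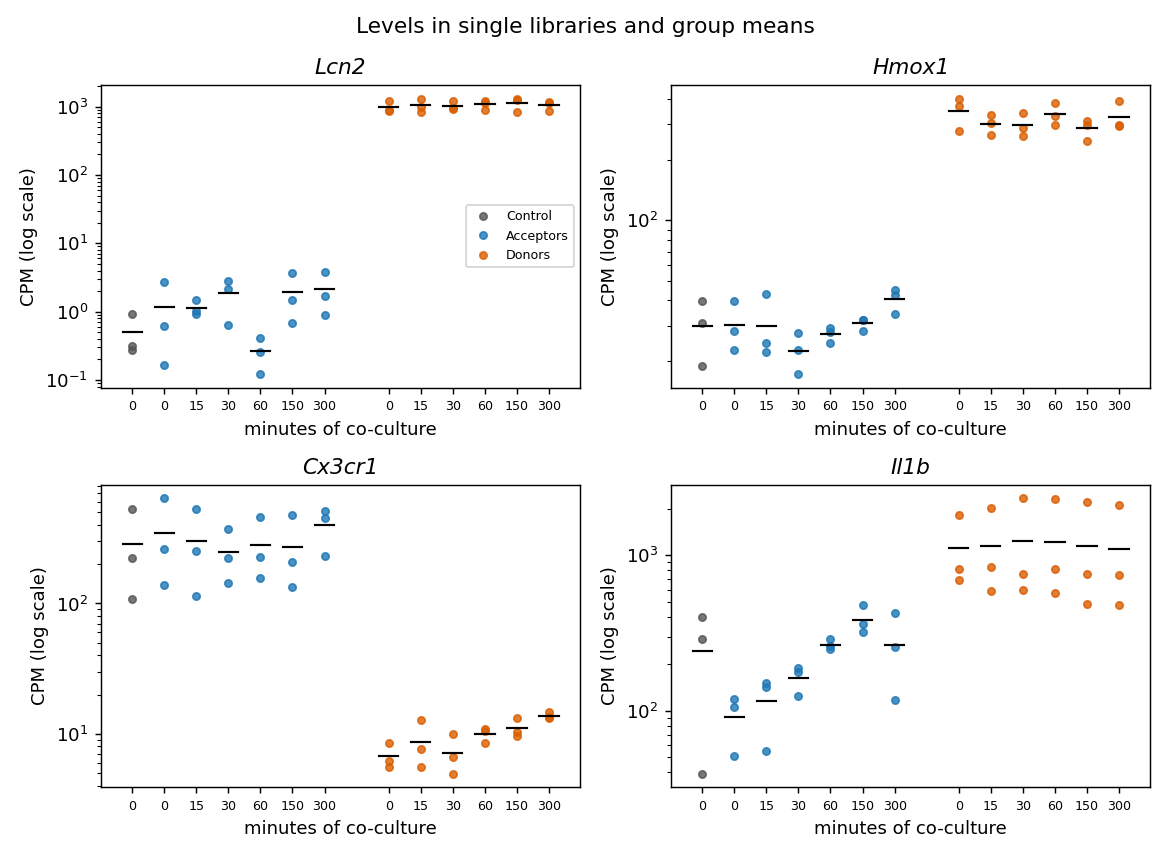
CPM of Lcn2, Hmox1, Cx3cr1 and Il1b on logarithmic vertical axes in single libraries (points) and as group means (lines), with the control at 0 min, then acceptors and then donors at 0 to 300 min of co-culture along the horizontal axes. Lcn2 means are 982 CPM in donors at 0 min and 1049 at 300 min, and 0.500 in the control; Il1b in donors spreads from 689 to 1826 CPM at 0 min.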

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

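The tests of donor RNA in the acceptors, of handling and of regroupings within runs of library numbers were chosen only after the rise of Cytip and Vegfa was seen, and the test of a shift toward the donor profile was set beforehand. Groups of 3 libraries were not tested for outlying samples. The entries here are differences between donors and acceptors in how they changed over time, each tested as a difference.

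Cytip and Vegfa differed between the populations in their time courses (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p = 0.00732 and 0.0150). Cytip went from 7.32 to 85 CPM between 0 and 150 min in acceptors and from 22.5 to 14.0 in donors, and Vegfa from 4.73 to 21.8 in acceptors and from 25.4 to 18.6 in donors. Over the alternatives the adjusted p of Cytip lay between 3.35e-08 and 0.0343 and that of Vegfa between 3.82e-06 and 0.0561. Vegfa missed the threshold, and the count of such genes became 1, without donor replicates 2 or 3 at 60 min and without acceptor replicate 2 at 0 min. Of 100 regroupings of the time labels within each population, 1, the real one, gave as many genes, the highest other giving 1 gene. Of 100 regroupings within runs of library numbers, 1, the real one, gave as many (2, highest other 1, and with the replicate block 4, highest other 2). Both kinds of regrouping moved time labels in donors and in acceptors. They thus stand for no change over time in either population, and not for equal time courses. Leaving out any of the libraries named above brings the real count to 1, as high as the highest other without the block. The real grouping gave more genes than any other, but this does not settle whether chance is excluded.

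A candidate explanation for the rise in acceptors is RNA or cells from donors in the acceptor libraries. The tables argue against it. To give the Vegfa level, donors would need to make up 123% of the acceptor library and would bring 1386 CPM of Lcn2. Acceptors at 150 min had 1.93 CPM of it, 0.140% of that, and Cytip in acceptors exceeded its level in donors. A general shift of acceptors toward the donor profile was not seen either. Genes higher in donors than in control at 0 min did not rank higher in acceptors at 150 min (camera p = 0.686; p = 0.820 with an estimated correlation). Handling or a change of medium cannot be told apart from co-culture, as 0 libraries of this series hold acceptors kept alone for these times, and a response of the acceptors to the donors stays open as an untested biological explanation.

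Immediate early genes moved differently in donors and acceptors at 60 min (camera adjusted p = 3.59e-05; adjusted p = 0.359 with an estimated correlation), with a median change of −0.09 log2 units in donors and 0.46 in acceptors. At 300 min they differed too (camera adjusted p = 0.0261; adjusted p = 0.994 with an estimated correlation), with medians of −0.58 in donors and −0.02 in acceptors. Endocytosis and phagocytosis receptors differed at 150 min (camera adjusted p = 0.0235; adjusted p = 0.0482 with an estimated correlation), with medians of −0.18 in donors and 0.10 in acceptors. The estimated correlation of this list was −0.0145, below the preset 0.01, so for it the second test was not a stricter one.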

How the results depend on the processing

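Of the alternatives here, scaling by total counts, leaving out Rn45s, leaving out acceptor replicate 2 at 300 min and the alternatives for the overlap of 0 and 300 min were chosen after seeing the data. No named gene reversed direction. The list tests were rerun only with an estimated correlation and with the replicate block, and none reversed direction there. Under total-count scaling the balance of called members turned for lysosome, heat shock and chaperones, and endocytosis and phagocytosis receptors in donors against control. In donors against acceptors at 300 min it turned for actin and membrane tubes, from 4 higher and 2 lower to 2 and 8. It also turned there for apoptosis and p53, from 10 and 6 to 6 and 7. For the 19 counts, RLE scaling, no filter on low counts, a filter of 1 CPM in 3 libraries and leaving out Rn45s kept each within 1.5 times its reported value. Where a count moved further, the cause was not tested. With DESeq2, acceptors against 0 min had 6 genes called at 60 min, 5 at 150 min and 5 at 300 min, and the tests over time 34 in acceptors and 1 in donors. Fits to the compared groups alone, which have fewer libraries to estimate the spread, called 5 genes at 60 min and 0 at 300 min in acceptors and 1 over time in acceptors. They called 719 for donors against acceptors at 300 min, which holds the doubted acceptor library, and 659 at both 0 and 300 min. Fits of the same size kept donors against control at 0 min and at 300 min within 1.5 times the reported count. The same held for donors against acceptors at 0 min. Having fewer libraries does not by itself account for the 719. Limma on the normalized counts, total-count scaling and leaving out the doubted acceptor library each called 0 genes in acceptors at 300 min, where the reported count is 1.

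The labels give no replicate numbers, so the pairing rests on the library numbers and the data: 37 of 39 libraries correlated best with libraries of their own run of library numbers (mean correlation of deviations 0.154 within and −0.0760 between runs). Deviations were taken from the mean of each group, which holds 1 library per run. A negative value between runs therefore follows from a positive one within runs and adds nothing to it. Without the doubted acceptor library, which is not in donors against control at 0 min but enters the shared estimate of the spread, that comparison had 8 higher and 3 lower of heat shock and chaperones, 2 and 17 of cell cycle, 6 and 3 of actin and membrane tubes, 0 and 5 of ribosomal proteins and 1 and 2 of oxidative phosphorylation. With the replicate block, donors at 300 against 0 min had 1 gene called, acceptors 2 at 60 min, 8 at 150 min and 8 over time, and 4 genes had different time courses. The block ended no call of the 44 list tests and added 10, 3 of them in comparisons that the runs pair, whereas with an estimated correlation 5 were kept and 39 lost.

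Leaving out 1 library of a comparison moved the counts as follows. Donors against control at 0 min gave 1664 (without control replicate 2) to 2211 genes, and donors against acceptors at 0 min 1954 (without acceptor replicate 2) to 2506. Acceptors against 0 min gave 0 to 2 genes at 60 min, 0 to 2 at 150 min and 0 to 19 at 300 min (19 without replicate 3 at 300 min). The count of genes with different time courses was 1 to 2, the 1 arising without donor replicates 2 or 3 at 60 min or acceptor replicate 2 at 0 min. Of the genes named for donors against control at 0 min, 87 of 108 called genes kept their call under all alternatives, and 74 of 114 for donors against acceptors at 300 min. Depth limits genes near the floor of 0.181 to 0.414 CPM.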

Other observations

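The tests of other cell types, of the culture vessel and of GC content, of few distinct molecules, of donor RNA in 1 acceptor library and of regroupings within runs of library numbers were chosen only after the results were seen, and the test of scaling and the regroupings of libraries were set beforehand.

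Mmp13, a collagenase chosen after its values were seen, had 3281 ± 686 CPM in donors and 48.8 ± 19.5 in the control at 0 min, and 2589 ± 576 in donors at 300 min (SD, n = 3 each). Thbs1, the matrix protein thrombospondin 1, likewise chosen after its values were seen, had 76.3 ± 11 CPM in donors at 0 min. In acceptors it had 1.37 ± 0.962 at 0 min and 12 ± 2.90 at 150 min, without a call over time in acceptors (edgeR Benjamini-Hochberg adjusted p = 0.177), but with one under the replicate block (adjusted p = 0.0177). Il1b in donors had 1 library per time that stood above the others, with 1826 CPM at 0 min, 2033 at 15 min, 2327 at 30 min, 2291 at 60 min, 2203 at 150 min and 2098 at 300 min. These 6 libraries belong to the same run of library numbers. The other 2 libraries of each time lay between 477 and 844 CPM.

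Donors differed from control at 0 min in 2565 genes. A few very abundant transcripts could shift the scaling. With total counts and without the 20 most abundant genes 85.6% of the called genes kept their call and direction (72.4% of the higher, 100% of the lower). Under this setting the median log2 change of all genes was −0.228, which favours lower calls, and 34.4% of its 2825 calls were higher. The share kept among lower genes therefore says little. The 72.4% kept among higher genes argues against scaling as the whole cause. RNA of other cell types would bring their markers. Tested were 57 markers of astrocytes, oligodendrocyte lineage, neurons, fibroblasts and vessels and other immune cells. Together they changed by −0.0870% of the 271434 CPM gained by the higher genes. These markers summed to 806 to 1022 CPM in single control libraries and 603 to 712 in donors at 0 min. A change within that range would be a small percentage in either direction, so the percentage alone decides little. Their most abundant members, Mfge8 at 126 CPM in donors and 285 in control and Cnp at 131 and 104, did not rise together. The vascular marker Kdr went from 46.7 CPM in control to 104 in donors without a call, Dcn and Pecam1 (0.364 CPM in control and 6.44 in donors) were called, and so was S100a8 of other immune cells (0.414 and 48.6). A change in fibroblast, vascular or other immune cell RNA therefore stays open for part of the genes. The culture vessel and plating density cannot be told apart from a response to alpha-synuclein, which stays open too, as 0 libraries of this series hold cells plated as donors without it.

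Acceptors at 300 min replicate 2 stood apart from the other 17 acceptor libraries. It may hold few distinct molecules, a hypothesis found on the same data: reduced to 8649169 reads each, it had 11951 genes with reads and the others 12597 to 13790. Donor RNA is argued against by Lcn2 at 1.70 CPM and Saa3 at 1703 CPM, within the others' 0.123 to 3.74 and 1106 to 5343. Whether GC content plays a part stays open, since the rank correlation across genes of its deviation with GC content was 0.267, outside the others' −0.176 to 0.104 but short of the size set for a cause, and genes are not independent replicates. No biological explanation was tested.

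Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. For donors against control at 0 min the real split gave 2565 genes and the highest other 0, and for donors against acceptors at 0 min 2975 and 0. For donors at 300 min against control they were 2356 and 0, and for donors against acceptors at 300 min 3002 and 772; in each, 1 of the 10 splits, the real one, gave as many. For acceptors against 0 min the real split gave 1 gene at 60 min, 2 at 150 min and 1 at 300 min, with 0 as the highest other and 1 of 10 splits as large. Where the real split gave 0 genes, all 10 splits are as large, the highest other giving 1 gene for donors at 15, 60 and 150 min and 0 for acceptors against control, donors at 30 and 300 min and acceptors at 15 and 30 min. For the F test in donors the real count is 0, so all 100 regroupings are as large and decide nothing, the highest other giving 26 genes. In acceptors 6 of 100 gave at least its 2 genes, so chance is not excluded by regroupings that ignore the runs. The highest other, 182 genes, came from a regrouping in which 0 of 6 groups held all runs of library numbers. The other regroupings with 0 such groups gave 0 to 2 genes, so this make-up alone does not account for it. What else it follows was not tested. Within runs, 1 of 100 regroupings of acceptors, the real one, gave as many (2, highest other 1, and with the replicate block 8, highest other 2). Regroupings that keep the runs thus gave fewer genes than the real one, but they were chosen after the results were seen. Beside the 6 of 100 from the regroupings set beforehand, they do not settle whether chance is excluded.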
